A study of Mus musculus with 10 samples.

How the data were processed

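Mouse liver RNA was measured by RNA sequencing in 10 libraries. The labels place the libraries in 3 groups by the parents' genotype. Controls (4 libraries) came from parents that both carried the floxed insulin receptor gene without Albumin-Cre. FL offspring (3 libraries) had a LIRKO father, a mouse lacking the insulin receptor in hepatocytes, and a control mother. ML offspring (3 libraries) had a LIRKO mother and a control father. The labels do not give the offspring's own genotype, sex, age, litter or diet. Each library is labelled as a separate sample, and nothing in the labels says outright that each is a separate animal, so p-values measure the spread between these libraries. Replicate numbers run from 1 to 10 over the series, share no number between groups and pair nothing.

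The deposited table holds raw counts of reads per gene. Per the labels' protocols, polyadenylated RNA was made into directional libraries and sequenced as paired ends on an Illumina HiSeq instrument. Per the submitters' processing notes, the authors used STAR, featureCounts and the GRCm38 build. Versions, the annotation release and the strand setting of the counting are not given in the sources used here. Reads of overlapping genes, antisense genes and near-identical family members, such as the Mup, Cyp2b, Cyp4a and haemoglobin genes, are therefore uncertain. Totals ran from 18655506 to 39379940 counts per library. The table has 46071 gene rows. Of these, 45229 matched GENCODE M21 on GRCm38 by identifier, which supplied symbols, coordinates, exon length and GC content. The 842 others held at most 0.0659% of any library's counts.

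Gene tests used edgeR 4.0.16 (R 4.3.3). TMM factors, filterByExpr with a minimum count of 10, and a quasi-likelihood F test with robust dispersion were applied to all 10 libraries, with a coefficient per group. This left 14820 genes and 7 residual degrees of freedom, and the common biological coefficient of variation was 0.448. A gene passed at a two-sided Benjamini-Hochberg adjusted p under 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of F. CPM values are scaled by the TMM factors.

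Before the data were examined, 44 gene lists were fixed, 30 for pathways and 14 for cell types, together with the design, the alternatives and the rule for naming genes. The 41 lists with at least 5 tested members were tested with camera (limma 3.58.1) on voom values at a preset correlation of 0.01, adjusted over the lists. The 3 others, sex chromosome genes, pancreatic acinar cells and skeletal muscle, had too few. Counts of members that passed adjusted over the list alone are given for lists already called, and are not corrected over the lists. Members of a list can move together, so these counts add no separate evidence. The naming rule took up to 12 genes per direction past the threshold with a mean CPM of at least 1 and no overlap between groups. Where fewer than 5 genes passed, it took the 10 with the lowest p. It added Insr, Nnat, H19, Igf2 and the lowest-p members of each list described. Genes with Gm or Rik symbols were not named, and the results of some list members are not reported here.

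Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, other scaling factors, other filters, a fit of the compared groups only, a looser threshold, a surrogate variable (sva 3.50.0), camera with an estimated correlation, fry, and leaving out each library. Added after seeing the data were leaving out control 1 and ML 9 together, removing a per-library trend on exon length and GC content, sample quality weights, and a surrogate variable in the list tests, with the preset or the estimated correlation. An adjustment for sex was planned only if a group held both sexes, and was not run.

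The procedure was tested on simulated counts with 200 changed genes per comparison. For FL against control, over 14604 genes, it recovered 2% of genes changed 2-fold, 50% at 4-fold, 78% at 8-fold and 92% at 16-fold. For ML against control, over 14628 genes, these shares were 6%, 42%, 72% and 92%. For FL against ML, over 14616 genes, they were 4%, 38%, 82% and 96%. Of 117, 107 and 115 calls, 6, 1 and 5 were of unchanged genes, and no list was called. The simulation had no correlation between genes. Pairs of libraries within a group differed by more than counting noise (chi-square per degree of freedom 90.6 to 630), so none was counted as a repeat of another.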

Results

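Liver transcriptomes were compared between control offspring, offspring of LIRKO fathers (FL) and offspring of LIRKO mothers (ML), to ask whether a parent's lack of hepatic insulin receptor is followed by a change in the offspring's liver. Totals were 18655506 counts in control 1, 37292273 to 39379940 in the other controls, 23192571 to 31116742 in FL and 26614915 to 34568205 in ML. Coordinates are on GRCm38.

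The insulin receptor gene Insr (ENSMUSG00000005534, chromosome 8, 3122061 to 3279617) was present in all 10 libraries. Controls had 1103, 3227, 4954 and 3082 counts, FL had 2096, 2049 and 2041, and ML had 2072, 432 and 1779. Mean CPM was 85.6 ± 29.5 (SD, n = 4) in controls, 65.5 ± 10.5 (SD, n = 3) in FL and 45.9 ± 15.4 (SD, n = 3) in ML. Insr did not pass in any comparison, with a log2 fold change of -0.39 (SE 0.34) in FL and -0.90 (SE 0.34) in ML against control. It was at -0.13 in FL without control 3, and at -0.34 in ML with a trend on exon length and GC content removed, or -0.52 with a surrogate variable. The deleted part of the gene is not given in the labels, so a count over the whole gene checks the offspring's genotype only in part. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had counts in every library.

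The first principal component held 53.2% of the variance and set ML 9 and control 1 apart from the others. Genes with under 1000 bp of exon lay above their mean by a median of 2.04 on the log2 scale in ML 9 and 0.68 in control 1. The share of counts on the 18S ribosomal RNA gene was 4.69% in ML 9, 2.10% in control 1 and 0.52 to 1.67% in the others.

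**Figure D1:**
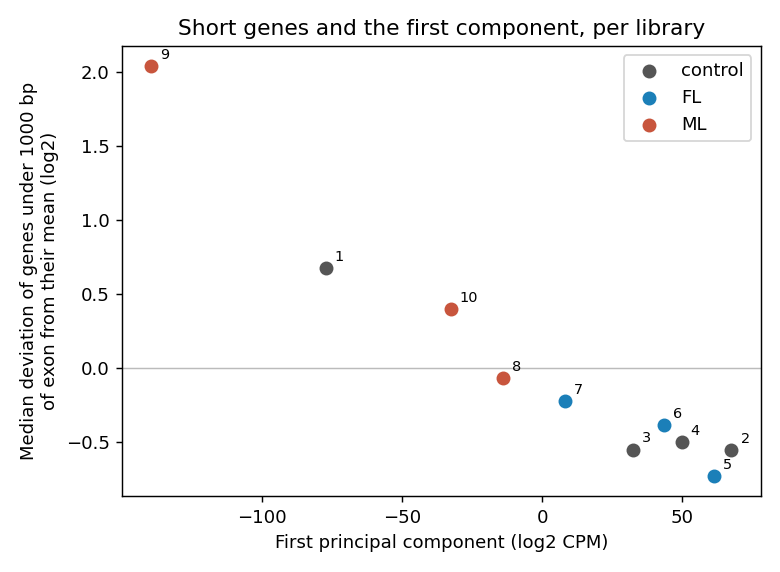
Each point is a library, with its replicate number, coloured by group. The x axis is the first principal component of log2 CPM and the y axis is the median log2 deviation of genes with under 1000 bp of exon from their mean over libraries. ML 9 lies at 2.04 and control 1 at 0.68.

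In FL livers, Moxd1 rose and Cyp2b9 fell against controls, and no other gene passed. Moxd1, a monooxygenase-like gene with male-biased expression in mouse liver (ENSMUSG00000020000, chromosome 10, 24223517 to 24302790), went from 0.168 ± 0.233 CPM (SD, n = 4) to 90.3 ± 60.0 CPM (SD, n = 3). Its log2 fold change was 8.97 (SE 1.02) with an edgeR adjusted p of 0.0124. Cyp2b9, a female-biased cytochrome P450 (ENSMUSG00000040660, chromosome 7, 26173411 to 26210661), went from 8.95 ± 3.89 CPM (SD, n = 4) to 0.095 ± 0.059 CPM (SD, n = 3). Its log2 fold change was -6.51 (SE 0.72), also with an edgeR adjusted p of 0.0124, and it rested on 3, 5 and 1 counts in FL. For both genes the FL and control libraries did not overlap, as for 5.71% of all genes tested, where chance gives 5.71%.

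Of the other genes with the lowest p in FL, none passed. Ppp1r3g, a glycogen-targeting subunit of protein phosphatase 1, had 38.9 ± 8.09 CPM (SD, n = 4) in controls and 0.294 ± 0.094 CPM (SD, n = 3) in FL, with an edgeR adjusted p of 0.124. Cyp4a14, a fatty acid hydroxylase, had a log2 fold change of -6.23 (SE 1.23). Rgs1 was at -2.39 (SE 0.42) and Tcf24 at -4.07 (SE 0.79). Srm, which makes spermidine, was at 1.67 (SE 0.26), and Asns, which makes asparagine, at 2.75 (SE 0.52). Bhlha15 was at 5.42 (SE 0.93) and Mup-ps23, a Mup pseudogene whose reads other Mup genes can share, at 3.92 (SE 0.73). Without FL 5, Bhlha15 was at 3.15.

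Camera called 17 of 41 gene lists between FL and control, 13 lower and 4 higher. No call held with an estimated correlation, where the lowest adjusted p was 0.162. Immediate early genes, which respond within minutes to stimuli, were called lower: 27 of 28 members lay below 0 with a median log2 fold change of -1.34. None passed over all genes and 15 passed adjusted over the list alone, with Nr4a1 at -2.94 (SE 0.60) and Fosb at -3.99 (SE 0.86); adjusted p = 0.162 with an estimated correlation. Fatty acid oxidation and PPARA targets were called lower, 31 of 32 members lying below 0 at a median of -0.55. None passed over all genes and 4 passed adjusted over the list alone, with Cyp4a14 lowest in p and Cyp4a10 at -3.68 (SE 0.79); adjusted p = 0.162 with an estimated correlation.

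Male-biased liver genes were called higher in FL, 22 of 29 lying above 0 at a median of 0.32; adjusted p = 0.162 with an estimated correlation. Moxd1 passed over all genes and 5 members passed adjusted over the list alone, among which Elovl3, a fatty acid elongase, went the other way at -2.29 (SE 0.48). Female-biased liver genes were called lower, 16 of 19 lying below 0 at a median of -0.49; adjusted p = 0.264 with an estimated correlation. Cyp2b9 passed over all genes and 5 passed adjusted over the list alone, Cyp4a14 being a member of this list and of the fatty acid oxidation list.

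Gluconeogenesis and FOXO1 targets were called lower in FL, 16 of 18 lying below 0 at a median of -0.32; adjusted p = 0.311 with an estimated correlation. Igfbp1, an insulin-repressed binding protein, was at -5.22 (SE 1.19) and Ppargc1a at -1.27 (SE 0.48), and 1 member passed adjusted over the list alone. Lipid droplet and fatty acid uptake genes were called lower, with 17 of 25 below 0, Cd36 at -1.28 (SE 0.35) and Pparg at -1.09 (SE 0.30); adjusted p = 0.162 with an estimated correlation. Lipogenesis genes were called lower, with 16 of 25 below 0, and 5 passed adjusted over the list alone, with Elovl5 at -1.79 (SE 0.40); adjusted p = 0.341 with an estimated correlation. Cholesterol synthesis genes were called lower, with 19 of 25 below 0 and Hmgcs1 at -1.19 (SE 0.55), or -0.70 without control 3; adjusted p = 0.595 with an estimated correlation.

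Xenobiotic genes were called lower in FL, with 26 of 35 below 0; adjusted p = 0.392 with an estimated correlation. Cyp2b10 in that list was at -5.68 (SE 1.77), where control 2 had 11347 counts and the other controls 54 to 274. Without control 2 it was at -1.85. Bile acid genes were called lower, with 23 of 28 below 0, although Cyp2c70 at 1.10 (SE 0.26) and Cyp7b1 at 1.21 (SE 0.38) had the lowest p; adjusted p = 0.162 with an estimated correlation. NRF2 targets were called lower, with 21 of 26 below 0 and Gsta1 at -1.51 (SE 0.53); adjusted p = 0.264 with an estimated correlation. Adipocyte markers were called lower, with 6 of 8 below 0 and Fabp4 at -1.35 (SE 0.47), or -0.80 with quality weights; adjusted p = 0.337 with an estimated correlation. Oxidative phosphorylation genes were called lower, with all 48 below 0 and Cox6c at -0.84 (SE 0.63); adjusted p = 0.776 with an estimated correlation. That direction turned without control 1, where Cox6c was at 0.011 (-0.26 with a surrogate variable), and without control 1 and ML 9 (adjusted p 0.387). Mitochondrially encoded genes were called lower, with all 13 below 0 and mt-Atp6 at -0.68 (SE 0.41); adjusted p = 0.494 with an estimated correlation. That call was lost with a trend on exon length and GC content removed, at a median of -0.10 (adjusted p 0.814) and -0.29 for mt-Atp6, which was at -0.37 without control 1.

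Heat shock genes were called higher in FL, with 16 of 20 above 0 and Hsph1 at 1.20 (SE 0.58); adjusted p = 0.341 with an estimated correlation. Interferon response genes were called higher, with 29 of 39 above 0 and Irf1 at 1.37 (SE 0.37); adjusted p = 0.724 with an estimated correlation. Cholangiocyte markers were called higher, with 9 of 11 above 0 and Sox9 at 1.10 (SE 0.52); adjusted p = 0.595 with an estimated correlation. Without FL 5, Hsph1 was at 0.68 and Sox9 at 0.66.

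The trend removed was that on exon length and GC content, and the adjusted p of each list in parentheses came from camera at the preset correlation. With the trend removed, the call of oxidative phosphorylation (0.0758) was lost. With a surrogate variable, the calls of oxidative phosphorylation (0.553) and cholangiocyte markers (0.0597) were lost. With no filter on low counts, the calls of bile acid genes (0.110), NRF2 targets (0.0977) and oxidative phosphorylation (0.0692) were lost. Leaving out control 1 and ML 9, the call of cholangiocyte markers (0.0789) was lost. Without control 1, the direction turned for oxidative phosphorylation (0.617). Without control 2, the calls of NRF2 targets (0.244), interferon response (0.378), mitochondrially encoded genes (0.180) and cholangiocyte markers (0.114) were lost. Without control 3, the calls of cholesterol synthesis (0.289), bile acid genes (0.178) and adipocyte markers (0.128) were lost. Without control 4, the calls of lipogenesis (0.0758) and interferon response (0.171) were lost. Without FL 5, the calls of xenobiotic genes (0.324), interferon response (0.191), oxidative phosphorylation (0.651) and cholangiocyte markers (0.487) were lost. Without FL 7, the calls of cholesterol synthesis (0.0533), bile acid genes (0.0620) and mitochondrially encoded genes (0.0956) were lost. Where the call held with the trend removed, the median was 0.54 for male-biased genes. Where the call held without control 1 and ML 9, the medians were 0.56 for male-biased genes, 0.25 for interferon response, -0.10 for lipogenesis and -0.29 for mitochondrially encoded genes.

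Lists not called between FL and control were called after such changes. Ribosomal proteins lay lower at a median of -0.25 (adjusted p 0.241). They were called higher without control 1 (0.00764), without control 1 and ML 9 (1.02e-07, median 0.25) and with a surrogate variable (0.00362), and lower without control 2 (0.0416), control 3 (0.0484), control 4 (0.0107) or FL 7 (0.0168). Leaving out control 1 and ML 9 called 20 lists, with lipoprotein (0.0409), TGF-beta and matrix (0.0409), periportal (0.0392) and endothelial (0.0173) genes newly lower. In all, 12 lists were newly called by at least 1 change, 11 of them with 1 library left out.

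The count of 2 genes was 0 without control 1, FL 5, FL 6 or FL 7 and 1 without control 2 or control 4, and limma-voom called Moxd1 but not Cyp2b9. DESeq2 called 52 genes, 15 higher and 37 lower, and 523 genes had an unadjusted p under 0.05 where 741 were expected by chance. The 523 became 268 without FL 5, 1036 without control 1 and ML 9, and 424 to 1125 with settings that kept all libraries of both groups.

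**Figure D2:**
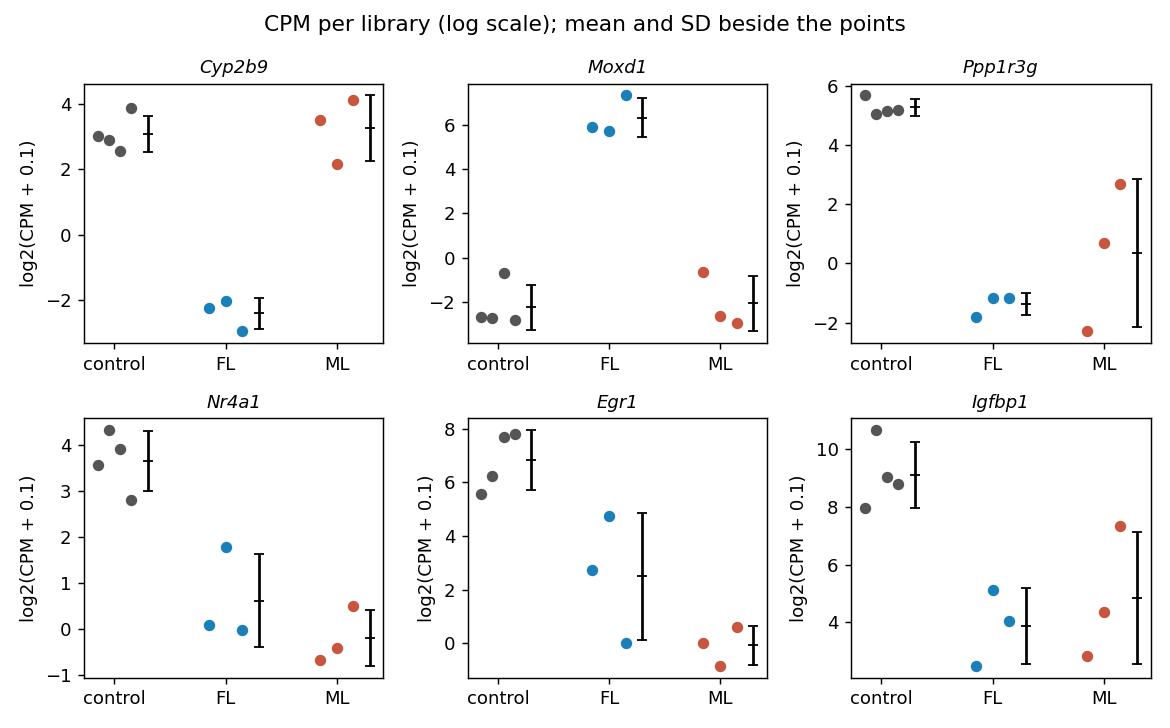
Each point is a library and each panel a gene, with log2(CPM + 0.1) on the y axis, the 3 groups on the x axis and the mean with its SD as a bar. FL libraries lie apart from the others for Cyp2b9 and Moxd1, and the controls lie above FL and ML for Ppp1r3g, Nr4a1, Egr1 and Igfbp1.

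In ML livers no gene passed against controls with edgeR, the lowest adjusted p being 0.301. At an unadjusted p under 0.05 there were 2392 genes, where 741 were expected by chance, and DESeq2 called 46, 10 higher and 36 lower. The 2392 became 669 without ML 9, 1093 without control 2, 1487 without control 3, 1114 without control 4 and 5177 without control 1. They became 4188 without control 1 and ML 9 and 382 with a surrogate variable. The count was 5153 with quality weights, 1418 with limma-voom and 1480 in a fit of the groups compared only. Without control 1, edgeR called 1 gene. Among the genes with the lowest p were several immediate early genes. Egr1 had 140 ± 91.9 CPM (SD, n = 4) in controls and 0.925 ± 0.486 CPM (SD, n = 3) in ML, a log2 fold change of -7.19 (SE 1.18). Nr4a1 was at -4.00 (SE 0.64), Fos at -4.62 (SE 0.88), Jun at -2.86 (SE 0.58) and Gdf15, a stress-induced cytokine, at -3.58 (SE 0.73). Frmd4b was at -1.93 (SE 0.40). Fosb and Ksr2 each had 1, 0 and 1 counts in ML, so no fold is given for them. Dmbt1 had 3846, 156 and 13 counts and Tff2 had 41, 103 and 14 counts in ML 8, ML 9 and ML 10, both secreted mucosal proteins with mean CPM of 0.096 and 0.101 in controls.

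Camera called 14 of 41 lists between ML and control, 9 lower and 5 higher, and no call held with an estimated correlation, where the lowest adjusted p was 0.619. Ribosomal protein genes were called higher, all 62 lying above 0 at a median of 1.57. None passed over all genes and 47 passed adjusted over the list alone; adjusted p = 0.706 with an estimated correlation. Nuclear oxidative phosphorylation genes were called higher, 45 of 48 lying above 0 at a median of 1.04, with Atp5o at 1.49 (SE 0.50), or 0.46 without ML 9 and 0.27 with a surrogate variable; adjusted p = 0.706 with an estimated correlation. The mean log2 CPM over both lists was 9.91 in ML 9, 8.52 in control 1 and 7.18 to 8.30 in the other libraries. With control 1 and ML 9 left out, the medians were 0.90 for ribosomal and 0.68 for oxidative phosphorylation genes.

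Immediate early genes were called lower in ML, 27 of 28 lying below 0 at a median of -2.05, and 13 passed adjusted over the list alone; adjusted p = 0.619 with an estimated correlation. Cholesterol synthesis genes were called lower, 23 of 25 lying below 0 at a median of -1.01, and 6 passed adjusted over the list alone; adjusted p = 0.619 with an estimated correlation. Dhcr7 was at -1.45 (SE 0.38). Lipogenesis genes were called lower, 20 of 25 lying below 0 at a median of -0.84, and 10 passed adjusted over the list alone, 9 lower and 1 higher; adjusted p = 0.619 with an estimated correlation. Scd1, a desaturase, was at -2.48 (SE 0.55) and Elovl5 at -1.73 (SE 0.40).

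Gluconeogenesis and FOXO1 targets were called lower in ML, with 13 of 18 below 0, Irs2 at -3.08 (SE 0.93) and Igfbp1 at -3.48 (SE 1.09), or -5.68 without ML 10; adjusted p = 0.706 with an estimated correlation. Insulin signalling genes were called lower, with 30 of 35 below 0, Irs2 being a member of both lists and Trib3 at -1.29 (SE 0.38); adjusted p = 0.706 with an estimated correlation. That call was lost with the trend removed, where the median went from -0.51 to 0.021 (adjusted p 0.385), and its direction turned with a surrogate variable (adjusted p 0.972). Endoplasmic reticulum stress genes were called lower, with 22 of 29 below 0 and Atf3 at -2.42 (SE 0.88), or -0.84 without control 2; adjusted p = 0.706 with an estimated correlation. Chromatin regulators were called lower, with 46 of 53 below 0 and Kmt2a at -2.24 (SE 0.63), or -1.41 with the trend removed; adjusted p = 0.706 with an estimated correlation. TGF-beta and matrix genes were called lower, with 38 of 47 below 0; adjusted p = 0.706 with an estimated correlation. Cell cycle genes were called lower, with 31 of 37 below 0, Foxm1 at -3.14 (SE 1.00) and Tk1 the other way at 1.77 (SE 0.64); adjusted p = 0.731 with an estimated correlation. The CPM of Tk1 was 28.2 in ML 8, 186 in ML 9, 59.8 in ML 10 and 13.5 to 48.0 in controls. Tk1 was at 0.73 without ML 9, and Foxm1 at -5.02 without ML 8. A surrogate variable put Irs2 at -1.14, Igfbp1 at -2.30, Atf3 at -1.27, Kmt2a at -0.78 and Tk1 at 0.39.

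T and NK cell markers were called higher in ML, with 11 of 14 above 0 and Cd3d at 2.65 (SE 0.77); adjusted p = 0.706 with an estimated correlation. The CPM of Cd3d was 0.814 in ML 8, 5.61 in ML 9, 0.620 in ML 10 and 0.204 to 0.684 in controls. Cd3d was at 1.00 without ML 9, and the list median went from 1.06 to 0.58 without control 1 and ML 9. Erythroid markers were called higher, with all 7 above 0 and Hba-a2 at 1.48 (SE 0.62); adjusted p = 0.706 with an estimated correlation. The CPM of Hba-a2 was 10.4 in ML 8, 66.0 in ML 9, 18.5 in ML 10 and 18.5 in control 1. Without control 1 and ML 9, Hba-a2 was at 0.71 (0.37 without ML 9 alone), and the median of the erythroid markers went from 1.37 to 0.59. Antigen presentation genes were called higher, with 11 of 16 above 0, H2-Eb1 at 1.59 (SE 0.47) and Nlrc5 the other way at -1.54 (SE 0.46); adjusted p = 0.706 with an estimated correlation. The CPM of H2-Eb1 was 38.6 in ML 8, 114 in ML 9, 20.5 in ML 10 and 15.9 to 24.7 in controls. H2-Eb1 was at 0.64 without ML 9, and Nlrc5 at -1.02 with the trend removed. A surrogate variable put Cd3d at 0.72, Hba-a2 at 0.15, H2-Eb1 at 0.70 and Nlrc5 at -0.76.

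With the trend removed, the calls of antigen presentation (0.201) and T and NK cells (0.0552) were lost. With a surrogate variable, the calls of gluconeogenesis (0.159), antigen presentation (0.0810), oxidative phosphorylation (0.0601), ribosomal proteins (0.0692), TGF-beta and matrix genes (0.0582), T and NK cells (0.221) and erythroid markers (0.661) were lost, and the direction turned for stress genes (0.776). In a fit of the groups compared alone, the call of antigen presentation (0.0750) was lost. Leaving out control 1 and ML 9, the calls of gluconeogenesis (0.139), antigen presentation (0.242), cell cycle (0.136) and T and NK cells (0.0895) were lost. Without control 1, the calls of gluconeogenesis (0.0856), antigen presentation (0.190) and cell cycle (0.0854) were lost. Without control 3, the calls of stress genes (0.0646) and cell cycle (0.149) were lost. Antigen presentation was also lost without FL 5 (0.0505), FL 6 (0.0522) or FL 7 (0.0536). Without ML 8, the calls of gluconeogenesis (0.0560) and antigen presentation (0.129) were lost. Without ML 9, the calls of insulin signalling (0.0601), gluconeogenesis (0.117), antigen presentation (0.112), stress genes (0.112) and erythroid markers (0.0533) were lost. Without ML 10, the calls of stress genes (0.0897), TGF-beta and matrix genes (0.0683) and cell cycle (0.151) were lost. Where the call held with the trend removed, the medians were -0.47 for lipogenesis, -0.23 for TGF-beta and matrix genes, 0.69 for erythroid markers, 0.64 for oxidative phosphorylation and -0.17 for chromatin regulators. Lists newly called with the trend removed were acute phase (0.00389) and mitochondrially encoded genes (0.00173), both lower. Without control 1 and ML 9 these were acute phase (0.0104), mitochondrially encoded (0.0380) and endothelial genes (0.0206), all lower, and female-biased genes (0.0282), higher. With a surrogate variable, female-biased genes (0.000101) and cholangiocyte markers (0.00425) were called higher, and heat shock genes (0.00841) and B cell markers (9.02e-05) were called after turning to higher and to lower. No list was called with a surrogate variable and an estimated correlation. In all, 14 lists were newly called by at least 1 change, 12 of them with 1 library left out.

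**Figure D3:**
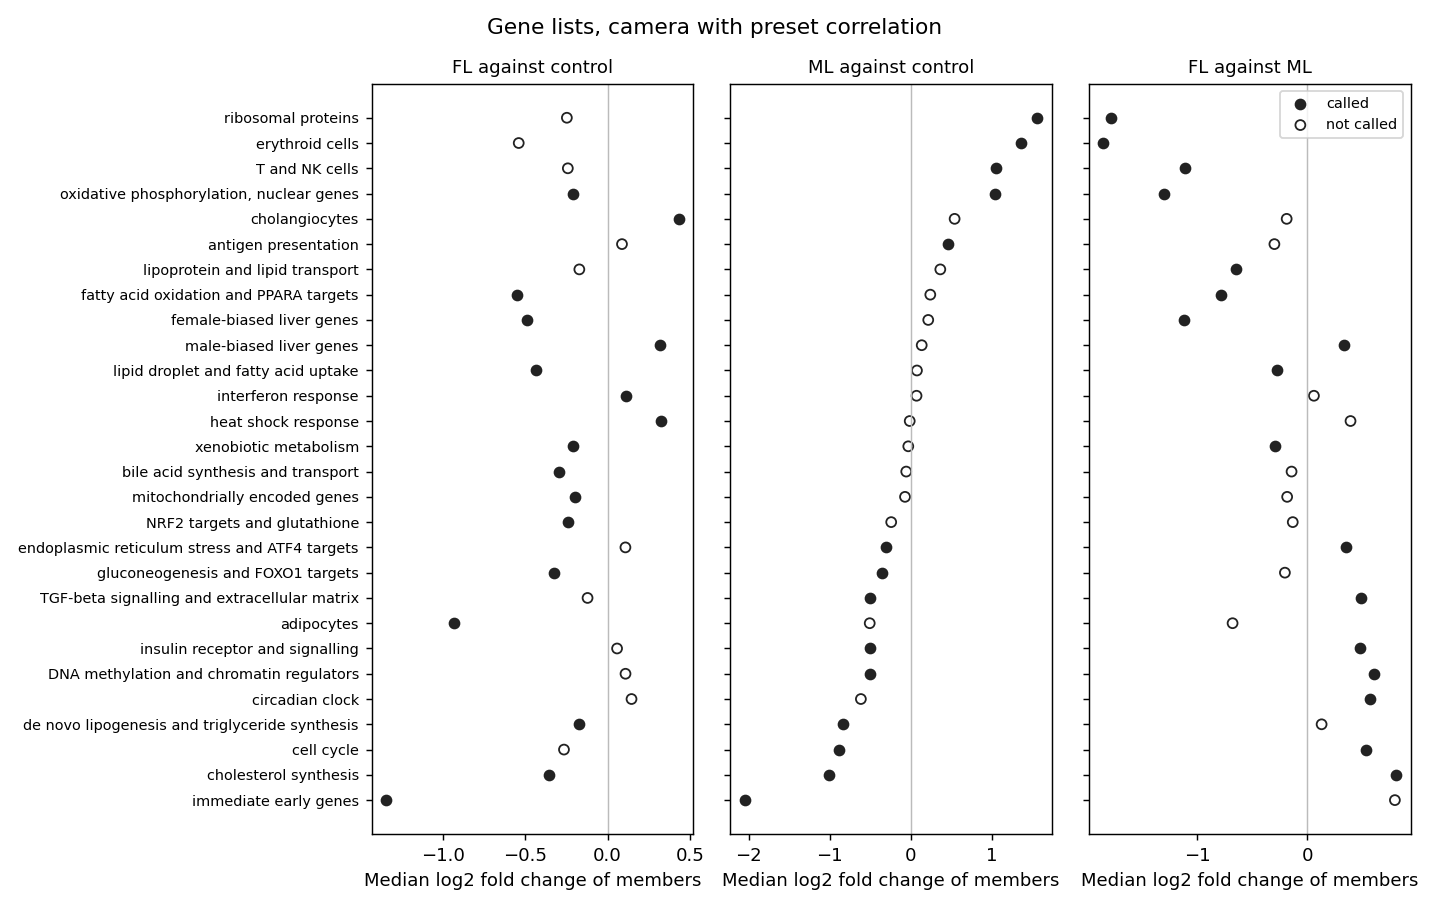
Each row is a gene list called in at least 1 of the 3 comparisons, and the x axis is the median log2 fold change of its members. Filled points were called by camera at the preset correlation and open points were not. Ribosomal proteins lie at 1.57 in ML against control and immediate early genes at -2.05.

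FL and ML livers, compared directly, differed in 1 gene. Cyp2b9 was lower in FL, at a log2 fold change of -6.81 (SE 0.74) with an edgeR adjusted p of 0.0144. The CPM of Cyp2b9 was 11.4, 4.37 and 17.3 in the ML libraries. Moxd1 was at 8.52 (SE 1.14) with an edgeR adjusted p of 0.0644 and did not pass, but passed without control 3 and with limma-voom. Also among the lowest p, none passing, were Acot3 at -4.07 (SE 0.70), Vnn1 at -1.96 (SE 0.39), Cyp4a14 at -6.24 (SE 1.25), Wfdc2 at -2.81 (SE 0.52), Tff2 at -4.63 (SE 0.95), Slc22a27 at -3.79 (SE 0.80) and Bhlha15 at 5.06 (SE 1.04). Tff2 was at -2.83 without ML 9 and -2.82 without control 1 and ML 9, and Bhlha15 at 2.80 without FL 5. A surrogate variable put Wfdc2 at -1.71, Tff2 at -2.43 and Bhlha15 at 2.97. The call of Cyp2b9 was lost without FL 5, FL 6, FL 7 or ML 8, with limma-voom, and in a fit of the FL and ML libraries alone. Groups did not overlap in 31.7% of genes, where chance gives 10%, and 2964 genes had an unadjusted p under 0.05, where 741 were expected by chance. The first principal component also separated these groups, at 8.06 to 61.5 in FL and -140 to -13.9 in ML. Genes that follow this component separate together, so 10% and 741 do not measure what groups without an effect would give here. The 2964 became 733 without ML 9, 882 without FL 5, 1817 without FL 6 and 277 with a surrogate variable. The surrogate variable was estimated from the same libraries and can take up part of a difference between groups. Values that shrank or turned with it therefore do not tell an artifact from a group effect. DESeq2 called 248, with no adjusted p for 12937 genes.

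Camera called 17 of 41 lists between FL and ML, 9 lower and 8 higher in FL. No call held with an estimated correlation, the adjusted p of each list then lying between 0.596 and 0.672. Lower in FL were ribosomal proteins, 62 of 62 below 0 at a median of -1.79, and oxidative phosphorylation, 46 of 48 at -1.31; adjusted p = 0.596 with an estimated correlation for each. Over the list alone 57 and 33 members passed, and with control 1 and ML 9 left out the medians were -0.62 and -0.56. With a surrogate variable the direction of ribosomal proteins turned (adjusted p 0.306). Fatty acid oxidation and PPARA targets were lower, 29 of 32 at a median of -0.78, and 11 passed adjusted over the list alone; adjusted p = 0.596 with an estimated correlation. Female-biased genes were lower, 16 of 19 at -1.12, and male-biased genes higher, 19 of 29 at 0.34, with Bcl6 at 2.63 (SE 0.65); adjusted p = 0.596 with an estimated correlation for each.

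Erythroid markers, with Hbb-bs at -3.40 (SE 1.11), and T and NK cell markers, with Cd3d at -2.95 (SE 0.87), were lower in FL than in ML; adjusted p = 0.596 with an estimated correlation for each. In ML 8, ML 9 and ML 10 the CPM was 130, 1513 and 176 for Hbb-bs and 0.814, 5.61 and 0.620 for Cd3d. Without control 1 and ML 9, Hbb-bs was at -1.42 and Cd3d at -1.28, and the median of the erythroid markers went from -1.86 to -0.78. Both genes shrank further with a surrogate variable, to -0.38 and -0.65. Xenobiotic genes, with Ces1d at -1.89 (SE 0.55), lipoprotein genes, with Vldlr at -2.36 (SE 0.58), and lipid droplet genes, with Cd36 at -1.38 (SE 0.36), were lower; adjusted p = 0.596 with an estimated correlation for each. The xenobiotic call was lost with the trend removed, where the median went from -0.30 to 0.012 (adjusted p 0.462). Cholesterol synthesis genes, 18 of 25 of which lay above 0, chromatin regulators, with Kmt2a at 2.24 (SE 0.65), insulin signalling genes, with Ptpn1 at 1.28 (SE 0.49), and stress genes, with Asns at 2.69 (SE 0.58), were higher; adjusted p = 0.596 with an estimated correlation for each. For insulin signalling the call was lost with the trend removed, where the median went from 0.48 to 0.033 (adjusted p 0.462), and the direction turned with a surrogate variable (adjusted p 0.521). With the trend removed Kmt2a was at 1.43 and Ptpn1 at 0.84. Clock genes, with Bhlhe40 at 1.95 (SE 0.49), were higher; adjusted p = 0.596 with an estimated correlation. TGF-beta and matrix genes, with Tgfbr2 at 1.57 (SE 0.48), were higher; adjusted p = 0.620 with an estimated correlation. With the trend removed their median was 0.15 in place of 0.49 and the call was lost (adjusted p 0.0933), and without FL 5 Tgfbr2 was at 0.99. Cell cycle genes, with Ccnd1 at 2.73 (SE 0.71), were higher; adjusted p = 0.672 with an estimated correlation. A surrogate variable put Ces1d at -0.998, Kmt2a at 0.69, Ptpn1 at 0.20, Bhlhe40 at 1.11, Tgfbr2 at 0.78 and Ccnd1 at 1.74.

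With the trend removed, the calls of lipid droplet genes (0.0523), lipoprotein genes (0.111), clock genes (0.0918) and T and NK cells (0.0949) were lost. With a surrogate variable, the calls of stress genes (0.598), TGF-beta and matrix genes (0.690), T and NK cells (0.248) and erythroid markers (0.0832) were lost, and the direction turned for clock genes (0.879). With no filter on low counts, the call of lipid droplet genes (0.0506) was lost. In a fit of the groups compared alone, the calls of lipid droplet genes (0.0618) and lipoprotein genes (0.0743) were lost. Leaving out control 1 and ML 9, the calls of lipid droplet genes (0.0895), lipoprotein genes (0.0895), clock genes (0.185), cell cycle (0.0834) and T and NK cells (0.0834) were lost. Without control 1, the calls of lipid droplet genes (0.0562), lipoprotein genes (0.0562) and cell cycle (0.0642) were lost. Without FL 5, the calls of xenobiotic genes (0.227) and TGF-beta and matrix genes (0.205) were lost. Without FL 6, the calls of lipid droplet genes (0.107) and clock genes (0.0654) were lost. Without FL 7, the calls of lipid droplet genes (0.0525), lipoprotein genes (0.0916), male-biased genes (0.125) and cell cycle (0.392) were lost. Without ML 8, the call of male-biased genes (0.177) was lost. Without ML 9, the call of clock genes (0.143) was lost. Without ML 10, the calls of lipid droplet genes (0.113), lipoprotein genes (0.0635), xenobiotic genes (0.251), TGF-beta and matrix genes (0.243) and cell cycle (0.258) were lost. Where the call held with the trend removed, the medians were 0.69 for male-biased genes, -1.03 for erythroid markers, -0.75 for oxidative phosphorylation and 0.21 for chromatin regulators. Lists newly called with the trend removed were acute phase (0.00578), heat shock (0.0175) and neutrophil genes (0.0306), higher in FL, and mitochondrially encoded genes (0.0117), whose median turned from -0.18 to 0.83. Immediate early genes (0.0227) turned to lower with a surrogate variable, and macrophage (0.0269) and B cell markers (0.0187) to higher. Interferon (5.17e-09) and neutrophil genes (0.00177) were then called higher, and gluconeogenesis (0.00596), periportal (0.000843) and adipocyte genes (0.00788) lower. No list was called with a surrogate variable and an estimated correlation. In all, 13 lists were newly called by at least 1 change, 11 of them with 1 library left out.

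With FL and ML combined against controls, no gene passed with edgeR at 0.05 and 6 did at 0.1. These were Ppp1r3g at -5.44 (SE 0.73), Nr4a1 at -3.47 (SE 0.47), Egr1 at -5.41 (SE 0.80), Fosb, Rgs1 at -2.14 (SE 0.33) and Cyp2b9, which was low in FL but not in ML. The lowest edgeR adjusted p was 0.0715, 792 genes had an unadjusted p under 0.05 and DESeq2 called 38. The 792 became 2856 without control 1 and ML 9, 2514 without control 1, 489 without control 2, 492 without control 4 and 494 without FL 7. With all libraries kept, the count was 2986 with quality weights and 1384 with no filter on low counts. Of the 6 genes, all but Cyp2b9 were lower in each FL and ML library than in each control. Such a lack of overlap was found in 0.978% of all genes tested, where chance gives 0.952%. The 6 genes were picked by low p in this comparison, so their lack of overlap adds no separate evidence. Without control 1, FL 6, ML 8 or ML 10, edgeR called 1 gene.

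Across the 14820 genes, which are not independent replicates, the log2 fold changes of FL and of ML against the shared controls correlated at r = 0.087. In a simulation, the counts of all 10 libraries, controls included, were drawn from the control means without any change, and r averaged 0.420. The covariance was 0.0447 against 0.130 in the simulation, a difference of -0.0854. Simulated genes were drawn independently of each other, unlike the measured ones, so these gaps decide nothing about agreement. With the controls split between FL and ML in 6 ways, r averaged -0.119 and ran from -0.591 to 0.236, so its sign depended on which controls were used. With a library left out it ran from -0.101 to 0.436, the highest being without control 1. At an unadjusted p under 0.05, 75 genes were lower in both FL and ML and 36 higher in both. Shared controls give some overlap without any change, and its size was not simulated, so these counts do not measure agreement.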

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

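The tests of explanations in this part were chosen after the results they bear on had been seen, and what the counts of other splits would show was not written down before they were run.

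Cyp2b9 differed between FL and ML, with a log2 fold change of -6.81 in the direct test, and 17 gene lists were called between these groups. No list was called with an estimated correlation, where the lowest adjusted p was 0.596. Outside the genes tested, Xist had 205 counts in ML 8 and at most 5 elsewhere, with Y-linked genes present in ML 8. H19 had 94 counts in ML 9 and at most 12 elsewhere.

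In the 4 controls, 75 measures were examined for a library far from the rest and 12 were found, where chance gives about 3.75. Many of these measures are related, and several genes among them were picked by low p in these same libraries. The 12 found are therefore no measured excess. Control 1 stood apart in its total of 18.7 M counts (18655506), in short genes (0.68 on the log2 scale) and in the mean log2 CPM of ribosomal protein genes (8.72), oxidative phosphorylation genes (8.25), antigen presentation genes (5.19), TGF-beta and matrix genes (2.44) and Srm (3.47). Control 2 stood apart in fatty acid oxidation genes (7.44). Control 3 stood apart in cell cycle genes (2.07) and Moxd1 (-0.79). Control 4 stood apart in Tcf24 (0.22) and in the share of counts on the 10 top genes (15.5%).

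Chance cannot be excluded for the genes and lists called in FL against control or the lists called in ML against control. For FL against control, 3 of 35 splits called at least the 2 genes of the real split, the highest other calling 82, and 8 of 35 called at least its 17 lists, the highest other calling 23. For ML against control, 15 of 35 reach its 14 lists, the highest other calling 21. Where the real count of genes is 0, each split must reach it, so all 35 splits for ML against control and all 100 drawn for FL and ML together say nothing about chance. The highest others called 3494 and 1610 genes. Splits that call so many genes point to a structure of the samples, and the split with 3494 genes put control 1, ML 9 and ML 10 in one group. Another split of ML against control, with 3459 genes, put control 1 and all ML libraries in one group and the other controls in the other. That split differs from the real one only in the place of control 1, so the real count of 0 genes depended on that place. The 10 splits of FL against ML are too few for a share under 0.05: 1 split reached the real 1 gene, the highest other calling 0, and 2 reached the real 17 lists, the highest other calling 18.

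Ribosomal protein and oxidative phosphorylation genes were higher in ML than in control by 1.04 on the log2 scale (SE 0.714, exact permutation p = 0.171). With the trend on exon length and GC content removed the difference was 0.81 (SE 0.525, exact permutation p = 0.143), and without control 1 and ML 9 it was 0.72 (SE 0.273). The 10 splits left without those libraries cannot give an exact p under 0.1, so that test decides nothing. Each remedy left over 50% of the difference, but the excess over 50% was smaller than its SE. These explanations therefore cannot be told apart from an effect of the mother's genotype, which stays open and untested.

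Immediate early genes were lower in FL and ML than in control by a mean of -1.56 on the log2 scale (SE 0.531, exact permutation p = 0.00952). The list was taken up after it was seen low in these libraries, and the permutation p is not adjusted over the 41 lists. For FL and ML together, no list was called by camera with an estimated correlation, where the lowest adjusted p was 0.300. Taken apart, neither group passed, with -1.33 (exact permutation p = 0.114) in FL and -1.79 (exact permutation p = 0.0571) in ML. With the trend on length and GC content removed it was -1.60 (exact permutation p = 0.00476, the smallest 210 splits can give), which argues against that trend. An index of evening-phase minus morning-phase clock genes differed by 0.16 (SE 0.498, exact permutation p = 0.786), too imprecise to settle whether livers were taken at another time of day. Pooling can hide opposite shifts: it was 0.898 to 2.21 in controls, 1.02 to 2.83 in FL and 0.490 to 2.11 in ML. By camera, clock genes were higher in FL (adjusted p 0.0812) and lower in ML (0.111), neither called. They were called higher in FL without control 2, control 3, FL 5 or FL 7. In ML they were called lower without control 4, without ML 10 or with no filter on low counts. Feeding state and handling at death follow no label and, with the parents' genotype, stay open.

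Low Cyp2b9 and high Moxd1 in FL go the male-biased way, so female animals as controls are a possible explanation. Each of the 4 controls had Cyp2b9 at 5.85 to 14.6 CPM and Moxd1 at most at 0.518 CPM. A single female among them would therefore not give the pattern. The lowest summed count of 4 Y-linked genes in a control or FL library was 2896, which argues against female controls. The summed mean CPM of the 4 other Cyp2b genes was -74.9 in FL relative to control, mostly from control 2. That excess in control 2 would hide reads of Cyp2b9 moving to a paralog, so the sum cannot decide this. Cyp2b9 lost 8.86 CPM from control to FL. In FL the mean CPM was 1.47 for Cyp2b10, 0.025 for Cyp2b13 and 0 for Cyp2b19 and Cyp2b23. These are too low to hold the lost reads, which argues against a move to these genes. The father's genotype, a difference in strain background, and age and litter, which the labels do not give, stay open and untested.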

How the results depend on the processing

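Length and GC removal, quality weights, the surrogate variable in list tests and leaving out control 1 and ML 9 were chosen after seeing the data. The cause of each change below was not tested. Genes called in FL against control numbered 2, and 52 with DESeq2, 1 with limma-voom, 1 without a filter, 4 with quality weights and 0 to 3 with a library left out. In ML against control they numbered 0, and 46 with DESeq2, 3 without a filter and 0 to 1 with a library left out. In FL against ML they numbered 1, and 248 with DESeq2, 2 without a filter, 2 at the looser threshold, 2 with the length and GC trend removed, 4 with quality weights, 0 in a fit of the groups compared only and 0 to 2 with a library left out. For FL and ML together they numbered 0, and 38 with DESeq2, 2 with limma-voom, 5 without a filter, 6 at the looser threshold, 5 with the trend removed, 7 with quality weights, 1 without control 1 and ML 9, and 0 to 1 with a library left out. Gene lists called fell to 0 in each of the 3 comparisons with an estimated correlation, with fry, and with a surrogate variable and an estimated correlation, and to 9 in ML against control with a surrogate variable. The correlation of fold changes was 0.463 without control 1 and ML 9, -0.119 on average with split controls (-0.591 to 0.236) and -0.101 to 0.436 with a library left out. Directions turned for oxidative phosphorylation in FL against control without control 1 and ML 9 (adjusted p 0.387; 0.000486 to 0.651 with a library left out) and for Cox6c (0.016; -1.05 to 0.011). With a surrogate variable, they turned in ML against control for insulin signalling (adjusted p 0.972, and 0.984 with an estimated correlation) and endoplasmic reticulum stress (0.776 and 0.915), and in FL against ML for insulin signalling (0.521 and 0.855), ribosomal proteins (0.306 and 0.930), clock genes (0.879 and 0.930) and Eif4ebp1 (0.038). Insr in FL against ML turned to -0.12 with the trend removed. Nnat in ML against control was -0.74 with limma-voom, -0.25 with the trend removed, -1.86 with quality weights, -1.12 without control 1 and ML 9 and -0.88 to 0.86 with a library left out. Nnat in FL against ML was 1.06 with quality weights, and for both groups together -0.94 to 0.32 with a library left out. Igf2 in ML against control was -0.32 with quality weights, -0.030 without control 1 and ML 9 and -0.14 to 0.38 with a library left out. Igf2 in FL against ML was 0.12 with quality weights and -0.45 to 0.079 with a library left out, and in FL against control -0.23 to 0.11. For both groups together Igf2 was -0.0337 with limma-voom, -0.26 with quality weights, -0.050 without control 1 and ML 9 and -0.10 to 0.16 with a library left out. For 160 gene results, settings other than leaving out a library gave 1704 values with the same sign and call. A further 97 were newly past the threshold, 4 no longer past it and 14 turned in sign. With a library left out, 1547 gene values kept sign and call, 8 were newly past the threshold, 14 no longer past it and 16 turned in sign. In the main fit only Moxd1 and Cyp2b9 in FL against control and Cyp2b9 in FL against ML had passed. For the other gene results the same call means still not called, so these counts do not measure stability. For 48 list results, settings other than leaving out a library gave 240 with the same direction and call, 181 no longer past the threshold and 11 turned in direction. These include the settings with an estimated correlation and with fry, where every call ended. With a library left out, 427 list values kept direction and call, 52 were no longer past the threshold and 1 turned in direction. The adjustment for sex was not run, because Y-linked genes had counts in every library, so these genes marked none as female. Whether ML 8, with 205 Xist counts, holds RNA of both sexes was not tested.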

Other observations

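Among lists that were not called, the 36 imprinted genes measured had 15 members above 0 and 21 below in FL against control, and the same numbers in ML against control (camera adjusted p 0.732 and 0.355). Nnat, an imprinted gene, was at 0.545 ± 0.460 CPM (SD, n = 4) in controls, 0.281 ± 0.118 CPM (SD, n = 3) in FL and 0.629 ± 0.640 CPM (SD, n = 3) in ML. Igf2 was at 0.408 ± 0.074, 0.393 ± 0.096 and 0.440 ± 0.167 CPM. H19 was too low to be tested. Hepatocyte markers had 4 of 14 members above 0 in FL (camera adjusted p 0.319) and 8 of 14 in ML (0.805). Growth hormone and IGF axis genes were divided evenly, 8 above and 8 below 0, in each of these comparisons (0.682 and 0.786). Acute phase genes lay below 0 in 22 of 31 in FL (0.939) and 23 of 31 in ML (0.135), although camera's direction in FL was higher. Without control 2 this list was called higher in FL (0.000920), and in ML it was called lower without control 1 (0.0311), control 4 (0.00151) or ML 9 (0.0401). B cell markers lay below 0 in 12 of 12 in FL (0.117), and were called lower without control 2 (0.000920), control 3 (0.0478) or FL 6 (0.0372).

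Igfbp1 and Elovl5 were lower in each FL and ML library than in each control. Of all genes tested, 0.978% did not overlap in this way, where chance gives 0.952%. In controls Elovl5 had 428 ± 176 CPM (SD, n = 4), against 124 ± 19.9 (SD, n = 3) in FL and 129 ± 32.3 (SD, n = 3) in ML. With FL and ML together, Elovl5 was at a log2 fold change of -1.76 (SE 0.32) with an edgeR adjusted p of 0.204, Igfbp1 at -4.35 (SE 0.85) and Pdk4 at -3.11 (SE 0.61), and none passed. Without control 2, where Pdk4 had 51.3 CPM against 3.76 to 12.9 in the other controls, it was at -1.92.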
